A study of Mus musculus with 13 samples.

How the data were processed

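H3K27ac, the acetylation of histone H3 at lysine 27 that marks active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in mouse bone marrow-derived macrophages, which are grown from marrow precursors with M-CSF. Per the labels, the cells came from animals that lack Il10 and Rag2, so they make no IL-10 of their own and the animals have no mature T or B cells. There were 4 groups of 3 libraries. Cells were left untreated, given LPS, the bacterial lipopolysaccharide, at 1 ng/mL for 195 min, given LPS with IL-10 at 1 ng/mL for the whole 195 min (continuous IL-10), or given LPS for 195 min with IL-10 in the last 30 min (late IL-10). Per the labels, the replicates came from 3 independent macrophage pools. An input library has no column in the deposited table and was not used here.

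Per the submitters' processing notes, Trim Galore, Bowtie2, MACS2, DiffBind and the mm10 build were used, and their roles, order and versions are not given in the sources used here. The authors deposited a signal value per library for each of 40691 consensus regions with a median width of 3062 bp. In each library, 100% of the values were whole multiples of that library's smallest value, within a tolerance of 0.0001 reads, so the deposited signal equals a whole number of reads times 1 scaling factor per library. No value was below 1 read, and between 19.7% and 29.9% of the regions of a library lay at exactly 1 read. Whether background or input reads were taken off before that floor was set is not given in the sources used here. A region of 29956 bp overlapping Adora2a lay at exactly 1 read in all 3 untreated libraries. Plain read counts would hardly give this, so reads were probably taken off. The reads recovered are then not the sequencing depth. A region at the floor is therefore not shown to be free of H3K27ac. Folds against it, also those given as lower bounds, describe the deposited values only. The reads recovered from all regions came to 12698228, 7208540 and 26922552 in untreated replicates 1, 2 and 3. They came to 5149730, 7242281 and 20884182 with LPS, 5926251, 7788604 and 10035619 with continuous IL-10, and 6635223, 7315345 and 11083204 with late IL-10. Median reads per region ranged from 18 to 89 across libraries, which limits the precision in weak regions.

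The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The design named edgeR for counts and limma for other units. As the deposited values are scaled, limma 3.58.1 in R 4.3.3 was used, with a mean-variance trend and robust moderation, on log2(value + 1) of all 12 libraries with the group as the only term. Fold changes on this scale understate the change of weak regions. Regions with a mean log2 value above the 10th percentile, 36621 in all, were tested, and calls were made at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p below comes from limma unless another tool is named. Values are means ± SD of 3 libraries. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so none was used for single genes. Where all libraries of a group lay at or under 3 reads per region, the fold is given as a lower bound computed against 3 reads per region and library.

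Libraries with the same replicate number deviated from their group means together. The correlation of these deviations was between 0.149 and 0.712 for 12 pairs of libraries, and 9 of the 12 were highest with their own number. With the 3 pools named in the labels, the numbers were taken to pair the libraries, and a fit with the replicate number as a block is given where it changes a call or moves a count by over 1.5 times. Correlations between replicates over regions were between 0.721 and 0.917, and the lowest was between LPS replicates 1 and 3.

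Genes were placed with a RefSeq gene table of the GRCm38.p6 assembly, the same build as mm10. The table gives no strand, so the start of a gene could not be told from its end. A region was assigned to every protein-coding gene it overlapped, or else to the nearest within 100 kb, in place of the planned nearest start site, and regions within 1 kb of either end of a gene were described in place of those near a start site. Of all regions, 27539 overlapped a gene, 10311 were assigned to the nearest and 2841 had none. A gene's value is the sum over its regions, and 13482 genes were tested. Neighbouring genes such as Tnf, Lta and Ltb, or Rsad2 and Cmpk2, share regions and are not independent. Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01. The 15 lists cover inflammatory cytokines, inflammatory effectors, the NF-kB pathway, the interferon response, IL-10 and STAT3 targets, immediate early genes, macrophage identity, housekeeping, lipid metabolism, and markers of T cells, B cells, neutrophils, dendritic cells, fibroblasts, and erythroid and mast cells. Sequence motifs were not searched because no genome sequence was used here.

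Genes were named by a fixed rule. The regions with the largest rise and fall among abundant calls whose groups did not overlap were taken, 8 each way, or 4 each way for the direct comparison of the IL-10 schedules. Up to 4 members of each list with a call in a comparison, and 14 genes chosen in advance, were added. Some results that the rule names are not reported here.

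The fit was tested on simulated reads for the real regions, made with the real means, library sizes and spread. Each library was drawn independently, so the simulated reads carry no pool effect. With 200 changed regions per comparison, none of the 2-fold changes was recovered. Of the 4-fold changes, 1.49%, 5.97%, 8.96% and 1.49% were recovered for LPS, continuous IL-10, late IL-10 and late against continuous IL-10, and of the 16-fold changes 28.8%, 28.8%, 34.8% and 39.4%. With a coefficient of variation 0.1 times as large, at least 98.5% of the 16-fold changes were recovered in each comparison, so the spread between libraries limits the calls. Unchanged regions made up 14 of the 113 calls over the 4 comparisons, or 12.4%, above the nominal 5%. With 5000 changed regions per comparison, they made up 4.32% of 6275 calls, and 66.0%, 64.6%, 64.9% and 67.0% of the 16-fold changes were recovered in the same order. Calls from comparisons with few changed regions are thus less certain than their adjusted p states. The rates of recovery and of false calls may differ in the data, where same-numbered libraries deviated together.

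Alternatives covered the scaling, the filter, the pseudocount, the libraries in the fit, the replicate block, DESeq2 1.42.0, the distances for genes, each library left out in turn and, chosen after seeing the data, edgeR 4.0.16 on the recovered reads, its fit with the block, the block with a pseudocount of 10, leaving out the 4 libraries numbered 3, and correlating the schedules from different pools. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.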

Results

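H3K27ac was profiled in mouse bone marrow-derived macrophages in 4 groups of 3 libraries, to ask how LPS changes the marked regions and what IL-10, an anti-inflammatory cytokine, does to that change. The groups were untreated, LPS for 195 min, LPS with IL-10 for the same 195 min (continuous), and LPS with IL-10 in the last 30 min (late). The libraries held between 5149730 and 26922552 reads in 40691 consensus regions, of which 36621 were tested. Gene values are sums of the deposited signal over the regions assigned to a gene, and changes are given as log2 differences.

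LPS raised H3K27ac at most of the inflammatory and antiviral genes examined. At Tnf, the gene of a central inflammatory cytokine, the value rose from 4424 ± 828 to 15914 ± 1206 (SD, n = 3), a log2 change of 1.86 (SE 0.19, adjusted p = 1.96e-05). At Il6 it rose from 4.45 ± 2.15 to 7825 ± 6545, at least 353-fold (adjusted p = 1.16e-04 from limma), with a wide spread between the LPS libraries. Cxcl10, which encodes a chemokine induced by interferon, rose by 4.86 (SE 0.37, adjusted p = 2.98e-06), and Ptgs2, the inducible cyclooxygenase gene, by 7.23 (SE 0.80, adjusted p = 4.09e-05). Il1b rose by 3.00 and Nos2, the inducible nitric oxide synthase gene, by 2.80. Pparg, a nuclear receptor gene expressed in resting macrophages, fell by 2.25 (SE 0.25, adjusted p = 4.61e-05).

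Of the 36621 regions tested, 6053 were higher and 6573 lower with LPS than without. Their median log2 changes were 3.84 and -3.56, or 3.65 and -3.19 with regions at the floor set to their bound. Coordinates are of mm10. The region at Adora2a, an adenosine receptor gene, overlaps the gene on chromosome 10 from 75313826 to 75343781. Its 3 untreated libraries lay at the floor, and its deposited value was at least 1860-fold higher with LPS, at 4082 ± 924. Here and elsewhere, such bounds hold for the deposited values only, not for H3K27ac itself. The region overlapping Marco, a scavenger receptor gene, on chromosome 1 from 120496610 to 120539490, was at least 1328-fold higher, and that overlapping Mrpl39 on chromosome 16 from 84696250 to 84722216 at least 3036-fold higher. Among the falls, the region overlapping Nxpe5 on chromosome 5 from 138220100 to 138232940 was at least 385-fold lower, and that overlapping Slco2b1, an organic anion transporter gene, on chromosome 7 from 99701501 to 99714011 was at least 297-fold lower.

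The lists of inflammatory genes moved upward with LPS. Of 28 inflammatory cytokine and chemokine genes tested, 23 rose and none fell (24 rose adjusted over the list alone), with a median log2 change of 2.65. Ccl5 rose by 4.04 and Cxcl9 by 5.09. Il12b rose by 4.36 (adjusted p = 0.0184), a call that ended without untreated replicate 3 or LPS replicate 1 or 2 (adjusted p = 0.0869, 0.0878 and 0.0768). Of 28 inflammatory effectors, 23 rose (25 adjusted over the list alone), among them the endothelin gene Edn1 at least 199-fold, Marco by a log2 change of 4.97, Ptges, a prostaglandin synthase gene, by 4.41 and Cd40, a co-stimulatory receptor gene, by 4.34. Of 21 genes of the NF-kB pathway and its feedback, 15 rose (15 adjusted over the list alone), including Nfkbia by 1.36, Nfkbiz by 2.14 and Traf1 by 2.90. Of 28 interferon response genes, 27 rose (28 adjusted over the list alone), including Ifnb1 by 1.68 (1 of its 4 regions fell, by 3.57), Irf7 by 3.28, Ifit1 by 4.33 and Rsad2 by 4.58. The camera adjusted p for these lists was 2.19e-13, 8.63e-18, 1.55e-07 and 2.76e-16 in the same order. None of these calls held with an estimated correlation, where they had adjusted p = 0.195, 0.0849, 0.245 and 0.195 with an estimated correlation.

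Genes of macrophage identity went both ways. Of 29 tested, 13 fell and 5 rose (15 and 5 adjusted over the list alone), with camera adjusted p = 0.0216 and adjusted p = 0.565 with an estimated correlation. Mpeg1, the perforin-2 gene, fell by 1.69 and Ctsd, a lysosomal protease gene, by 1.63, while Lpl, the lipoprotein lipase gene, rose by 3.70. The list's camera call ended without untreated replicate 2 (adjusted p = 0.0616) or LPS replicate 3 (adjusted p = 0.228). The count that fell was 8 without untreated replicate 3 and 7 without LPS replicate 1, and the count that rose was 2 without untreated replicate 1 or 2 or LPS replicate 2 and 3 without LPS replicate 1. Of 21 IL-10 and STAT3 targets, 6 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0502, or 0.0487 with the block and adjusted p = 0.620 with an estimated correlation). The camera adjusted p was 0.0494 without untreated replicate 2 and 0.0196 without LPS replicate 3, and 3 of the list rose without untreated replicate 1 or 2. Socs3, a feedback inhibitor of cytokine signalling, rose by 2.37 (SE 0.21, adjusted p = 1.01e-05) and Bcl6, a transcriptional repressor gene, by 2.21. Bcl3 fell by 0.76 (adjusted p = 0.0380) and Il1rn, the IL-1 receptor antagonist gene, rose by 1.71 (adjusted p = 0.0372). Both calls ended without each of the 6 libraries but LPS replicate 3, up to adjusted p = 0.150 and 0.151.

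Of 20 immediate early genes, Dusp2 (4.43), Egr2 (2.19) and Csrnp1 (1.13) rose and Fosb fell by 4.77 (3 and 1 adjusted over the list alone, 5 and 3 with the block; camera adjusted p = 0.804). The call for Csrnp1 ended without untreated replicate 1 or 2 (adjusted p = 0.0649 and 0.0886). Of 16 lipid and cholesterol genes, Ch25h, a cholesterol hydroxylase gene, rose by 5.11 and Mylip fell by 1.07 (1 and 0 adjusted over the list alone, 4 and 2 with the block; camera adjusted p = 0.961). The list median and mean were -0.29 and -0.03, while camera ranked the list upward. The call for Mylip ended without each of the 6 libraries but LPS replicate 2, up to adjusted p = 0.115. Of 18 housekeeping genes only Gapdh was called (1.46, adjusted p = 0.0367; none adjusted over the list alone, 3 higher and 3 lower with the block; camera adjusted p = 0.934). That call ended without untreated replicate 1 or 2 or LPS replicate 2 or 3, up to adjusted p = 0.162. Actb was 0.48 higher (adjusted p = 0.152) and passed without untreated replicate 3 (adjusted p = 0.0155).

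Markers of other cell types moved with LPS as well. Of 6 T cell markers tested, 5 rose (5 adjusted over the list alone, 5 higher and 1 lower with the block; camera adjusted p = 0.00423, adjusted p = 0.0849 with an estimated correlation). All untreated libraries were at the floor at Cd8b1, which was at least 60.6-fold higher with LPS, and at Cd3e, at least 17.1-fold higher. The tested region of Cd8b1 lies outside the gene, on chromosome 6 from 71316203 to 71321088. The values with LPS were 150.5 ± 80.9 at Cd8b1 and 47.2 ± 31 at Cd3e, against 15914 at Tnf. Cd247 rose by 5.39 and Lck by 1.87. Of 7 neutrophil markers, Camp rose by 7.57 while Elane fell by 6.55 and Mmp8 by 2.13 (1 and 2 adjusted over the list alone, 2 and 3 with the block; camera adjusted p = 0.550). The tested region of Elane also overlaps Prtn3, Cfd and Plppr3, that of Camp overlaps Nme6, and the called region of Mmp8 overlaps Mmp27. Here and with IL-10 below, these changes cannot be assigned to the markers alone. Of 9 dendritic cell markers, Bst2 (2.53), which interferon also induces, and Zbtb46 (1.32) rose, and 3 fell, among them Flt3 (-7.27) and Siglech (-3.16; 3 and 4 adjusted over the list alone; camera adjusted p = 0.804). The call for Siglech ended without untreated replicate 1 or 2 or LPS replicate 1 or 2, up to adjusted p = 0.105, and 1 marker fell without untreated replicate 1 or LPS replicate 1. Of 5 fibroblast markers, Dcn rose at least 140-fold and Pdgfrb fell by 0.69 (2 and 1 adjusted over the list alone, 2 and 1 with the block; camera adjusted p = 0.550). The called regions of Dcn lie outside the gene, on chromosome 10 from 97372195 to 97407104 (10.29) and from 97425975 to 97464261 (7.01). The tested region that overlaps Dcn, from 97481625 to 97483223, was not called (2.33, adjusted p = 0.139). The fall at Pdgfrb rests on a region shared with the macrophage gene Csf1r (-0.84), while its other region rose by 8.08, and both were looked up after the gene's value was seen. The call for Pdgfrb ended without untreated replicate 3 or LPS replicate 1 (adjusted p = 0.0890 and 0.121). Of 4 erythroid and mast cell markers, 1 rose, Gata2 by 3.89, and 2 fell, among them Cpa3 at least 12.3-fold (1 and 3 adjusted over the list alone; camera adjusted p = 0.443). The tested region of Cpa3, here and with IL-10 below, lies outside the gene, on chromosome 3 from 20197261 to 20198833. So does the called region of Gata2, while the tested region that overlaps Gata2 was not called (3.44, adjusted p = 0.0674). None of 4 B cell markers was called with limma (1 higher and 1 lower at an unadjusted p under 0.05, adjusted over the list alone and with the block; camera adjusted p = 0.934).

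**Figure D1:**
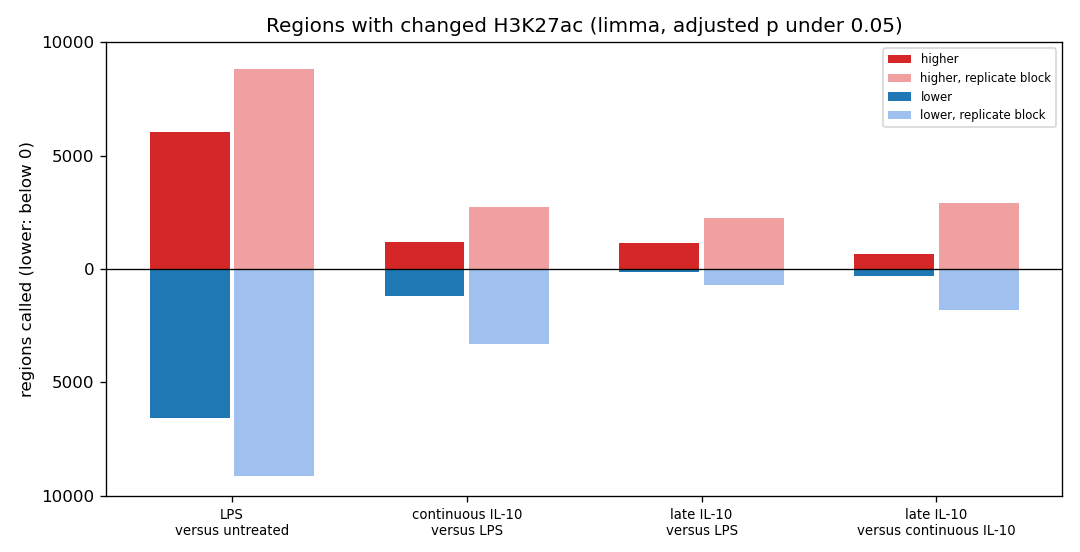
Number of regions called higher (above 0) or lower (below 0) in each of the 4 comparisons, without and with the replicate number as a block (limma, adjusted p under 0.05). LPS changed 6053 regions upward and 6573 downward, and late IL-10 raised 1149 and lowered 145.

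Continuous IL-10 left H3K27ac at part of the cytokine and interferon genes below its level with LPS alone. At Il6 all 3 libraries were at the floor, and the value was at least 198-fold lower than with LPS (6.57 ± 1.76 against 7825 ± 6545, n = 3; adjusted p = 0.00111 from limma). Among interferon response genes, Rsad2, the viperin gene, fell by 3.72 (SE 0.62, adjusted p = 0.00450), the transcription factor genes Irf7 by 2.32 (SE 0.37, adjusted p = 0.00326) and Stat2 by 1.68 (SE 0.30, adjusted p = 0.00668), and the interferon beta gene Ifnb1 by 1.99 (SE 0.37, adjusted p = 0.00766). Il4ra, the IL-4 receptor alpha gene, rose by 1.09 (SE 0.19, adjusted p = 0.00655). The calls for Il6, Rsad2, Irf7, Stat2, Ifnb1 and Il4ra held without each of the 6 libraries in turn, and those for Ifnb1 and Il4ra ended with median centring (adjusted p = 0.0520 and 0.0926).

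In this comparison 1201 regions were higher and 1186 lower than with LPS alone, or 2719 and 3287 with the replicate number as a block. Their median log2 changes were 3.44 and -3.78, or 3.04 and -3.29 with floors at their bound. Leaving out LPS replicate 1, 2 or continuous IL-10 replicate 1, 2 or 3 gave 763, 698, 602, 584 and 654 higher and 385, 373, 748, 521 and 576 lower regions, and leaving out LPS replicate 3 gave 2777 lower. Of the 1186 lower regions, 851 (71.8%) had been raised by LPS, and of the 1201 higher regions, 694 (57.8%) had been lowered by it. Among all regions tested, LPS raised 16.5% and lowered 17.9%. The same LPS libraries enter both comparisons, which favours such opposite calls. The region with the largest named fall lies on chromosome 5 from 29910297 to 29979424, 33690 bp from Il6, and was at least 700-fold lower. A region 21305 bp from Exoc6 on chromosome 19 from 37499245 to 37515458 was at least 251-fold lower. The region overlapping Zfp618, a zinc finger gene, on chromosome 4 from 63042912 to 63064022, was at least 721-fold higher, at 2568 ± 792.

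Of 28 cytokine and chemokine genes, 10 fell with continuous IL-10 and none rose (16 fell adjusted over the list alone, and 17 over all genes with the block), with a list median of -1.83. Of 28 interferon response genes, 11 fell (26 adjusted over the list alone, and 24 over all genes with the block), with a list median of -1.84. Camera gave adjusted p = 9.11e-13 and 3.52e-16, and both lists had adjusted p = 0.208 with an estimated correlation. Leaving out LPS replicate 1, 2 or 3 or continuous IL-10 replicate 2 or 3 gave 2, 2, 18, 3 and 6 cytokine genes and 6, 6, 20, 5 and 7 interferon genes. Tnf fell by 0.82 (SE 0.19, adjusted p = 0.0207), and its call ended without each library but LPS replicate 3, up to adjusted p = 0.0937, and with median centring (adjusted p = 0.140). Cxcl10 fell by 1.86 (adjusted p = 0.0113) and Il12b fell by 6.44 (adjusted p = 0.00977), and both calls ended without LPS replicate 1 or 2 or continuous IL-10 replicate 2, up to adjusted p = 0.0648 and 0.0578. Cxcl9 fell by 2.96, a call that ended without LPS replicate 1 (adjusted p = 0.0534) or continuous IL-10 replicate 2 (adjusted p = 0.0505). Il1b (-0.58), Nos2 (0.43) and Ptgs2 (0.51) did not pass the test, with 95% intervals of -1.83 to 0.66, -0.69 to 1.54 and -1.22 to 2.24. The sum at Nos2 hides a region within the gene, on chromosome 11 from 78945275 to 78956828, looked up after the gene's value was seen. That region was higher by 6.45 with continuous IL-10 (adjusted p = 8.02e-04) and by 7.52 with late IL-10 (adjusted p = 2.19e-04). No other tested region of Nos2 was called with either schedule.

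Of 28 inflammatory effectors, 3 fell, among them Cd40 (-1.72) and Icam1 (-1.07; 6 adjusted over the list alone, 7 with the block; camera adjusted p = 0.00966, adjusted p = 0.514 with an estimated correlation). The list's camera call ended without LPS replicate 1 or 2 or continuous IL-10 replicate 3 (adjusted p = 0.165, 0.181 and 0.178). The call for Cd40 ended without LPS replicate 1 or 2, and that for Icam1 without each of the 6 libraries, up to adjusted p = 0.0597 and 0.176. Of 21 NF-kB pathway genes, Map3k8, a kinase gene of the pathway, rose by 1.34 and Nfkbib fell by 1.19 (1 and 3 adjusted over the list alone, 2 and 7 with the block; camera adjusted p = 0.197, 0.0159 without LPS replicate 3, and adjusted p = 0.764 with an estimated correlation). The call for Map3k8 ended without LPS replicate 1 or continuous IL-10 replicate 1 or 2, up to adjusted p = 0.0661, and that for Nfkbib without each library but LPS replicate 3, up to 0.211.

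Of 21 IL-10 and STAT3 targets, Bcl3 (1.06), Il4ra (1.09), Nfil3 (1.22) and Hmox1 (0.79) rose (5 adjusted over the list alone, 8 with the block; camera adjusted p = 0.00466, adjusted p = 0.359 with an estimated correlation). The list's camera call ended without LPS replicate 3 (adjusted p = 0.177) or continuous IL-10 replicate 1 (adjusted p = 0.0558). The call for Bcl3 ended without LPS replicate 1 or 2 or continuous IL-10 replicate 1 or 3, that for Nfil3 without LPS replicate 1 or continuous IL-10 replicate 2 or 3, and that for Hmox1 without each library but LPS replicate 3, up to adjusted p = 0.125, 0.0758 and 0.194. Socs3 was 0.64 and Nfkbia 0.72 higher, and they passed with the block (adjusted p = 0.0289 and 0.0380) but not without it (adjusted p = 0.102 and 0.121). Of 29 macrophage identity genes, 3 rose, among them Fcgr3, an Fc receptor gene, by 1.31, and Apoe (5 adjusted over the list alone, 9 higher and 2 lower with the block; camera adjusted p = 0.00889, adjusted p = 0.359 with an estimated correlation). The list's camera call ended without LPS replicate 3 (adjusted p = 0.179) or continuous IL-10 replicate 1 (adjusted p = 0.0529). The calls for Fcgr3 and Apoe ended without LPS replicate 1 or any of the 3 continuous IL-10 libraries, and that for Apoe also without LPS replicate 2, up to adjusted p = 0.0945 and 0.163.

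Of 20 immediate early genes only Ier3 rose with continuous IL-10 (1.04; 1 adjusted over the list alone, 2 higher and 1 lower with the block; camera adjusted p = 0.809), a call that ended without LPS replicate 1 or continuous IL-10 replicate 1 or 3, up to adjusted p = 0.0723. No housekeeping, lipid, T cell, B cell or fibroblast gene was called with limma, against 0, 1, 3, 0 and 0 lower and none higher at an unadjusted p under 0.05. Adjusted over the list alone or with the block, 2 T cell markers were lower, and 1 lipid gene was lower with the block. The camera adjusted p of these lists was 0.134, 0.922, 0.0313, 0.876 and 0.296, and the T cell list had adjusted p = 0.208 with an estimated correlation and 0.0544 with the block. Its call also ended without LPS replicate 1 or 2 or continuous IL-10 replicate 3 (adjusted p = 0.0733, 0.0725 and 0.0874). The neutrophil markers Elane (4.91) and Mmp8 (1.31) rose (3 adjusted over the list alone; camera adjusted p = 0.0157, adjusted p = 0.208 with an estimated correlation), as did the mast cell marker Cpa3 (at least 7.27-fold; 1 adjusted over the list alone, 2 with the block; camera adjusted p = 0.0802, 0.0345 without LPS replicate 1, and adjusted p = 0.234 with an estimated correlation). The dendritic cell markers Zbtb46 (-1.52) and Batf3 (-1.84) fell (3 adjusted over the list alone, 5 with the block; camera adjusted p = 0.0802, 0.0159 without LPS replicate 3, and adjusted p = 0.327 with an estimated correlation). Each of these 5 calls ended without continuous IL-10 replicate 2, at adjusted p = 0.0819 for Elane, 0.139 for Mmp8, 0.110 for Cpa3, 0.0573 for Zbtb46 and 0.184 for Batf3, and without at least 3 of the other libraries.

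**Figure D2:**
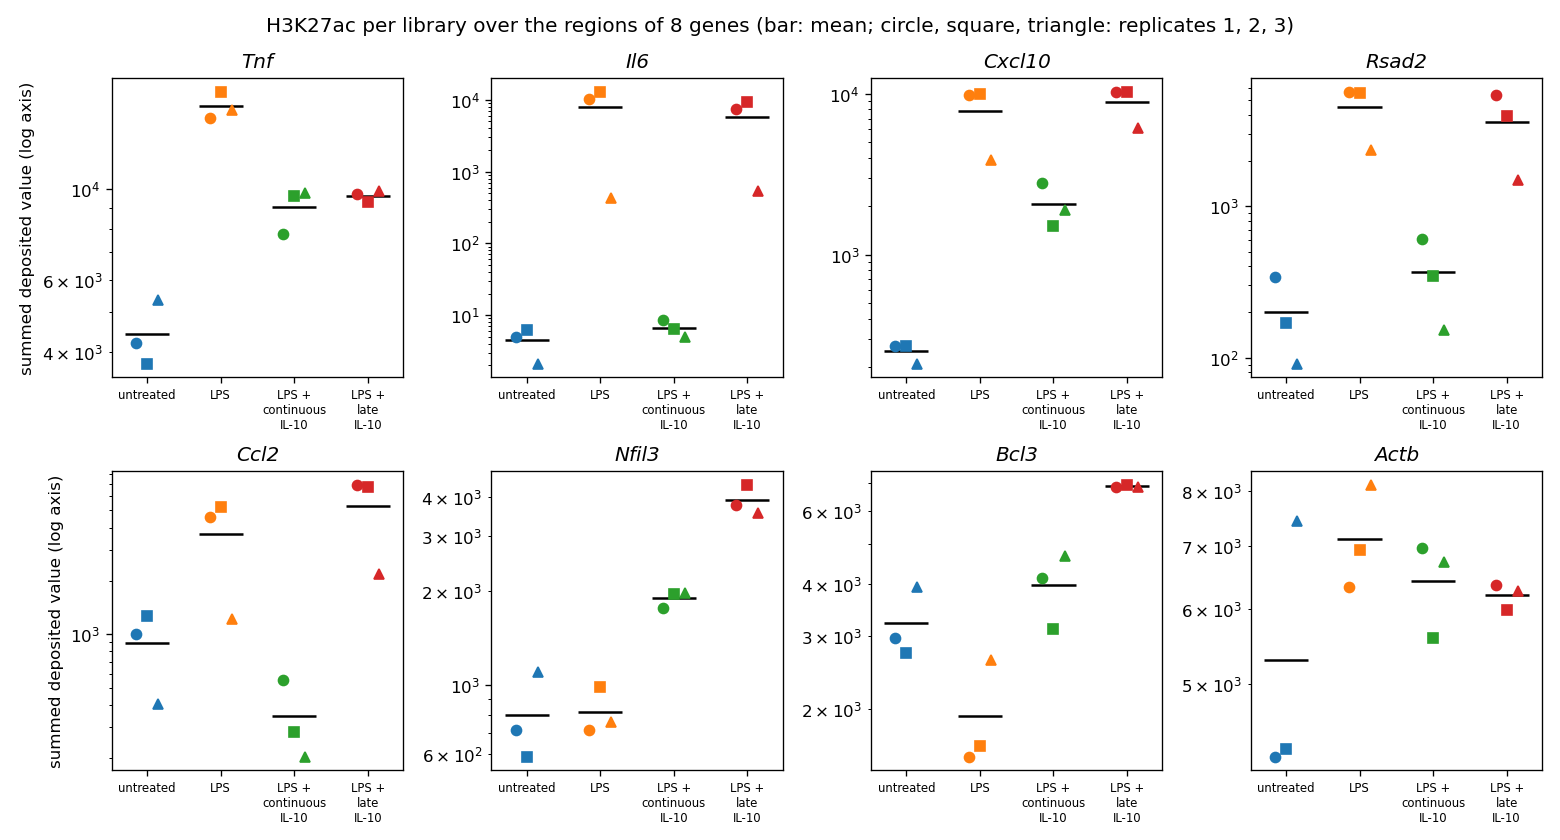
Summed deposited H3K27ac value (log axis) over the regions of 8 genes in each library of the 4 groups, with circles, squares and triangles for replicates 1, 2 and 3 and a bar at the mean. At Il6 the 3 libraries with continuous IL-10 had a mean of 6.57 against 5738 with late IL-10, while at Tnf the means were 9048 and 9638.

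With late IL-10 the called changes were mainly rises. Nfil3, a transcription factor gene, rose by 2.26 (SE 0.26, adjusted p = 3.49e-04), from 821 ± 142 to 3907 ± 426 (SD, n = 3). Etv3, a transcriptional repressor gene, rose by 1.91 (SE 0.23, adjusted p = 4.63e-04), Bcl3, an atypical member of the I kappa B family, by 1.87 (SE 0.25, adjusted p = 8.13e-04), and Il4ra by 1.59 (SE 0.19, adjusted p = 4.84e-04). Fcgr3 rose by 1.99, Ier3 by 1.60 and Map3k8 by 1.68. These 7 calls held without each of the 6 libraries in turn, and that for Map3k8 ended with median centring (adjusted p = 0.0799). Il6 (-0.20, 95% interval -2.83 to 2.43) and Cxcl10 (0.26, 95% interval -0.54 to 1.06) did not pass the test.

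There were 1149 regions higher and 145 lower than with LPS alone, or 2258 and 704 with the replicate block. Their median log2 changes were 3.85 and -3.35, or 3.53 and -2.76 with floors at their bound. Without late IL-10 replicate 1 or 2 there were 596 and 611 higher regions. Without LPS replicate 1, 2 or 3 or late IL-10 replicate 1, 2 or 3 there were 57, 42, 221, 38, 90 and 278 lower regions. The region overlapping Zfp618 was at least 441-fold higher, and that overlapping Cd244a, an immune receptor gene, on chromosome 1 from 171553400 to 171563810, at least 339-fold higher. A region 15496 bp from Babam2 on chromosome 5 from 32100446 to 32114909 was at least 422-fold higher. The region overlapping Cd2 on chromosome 3 from 101286510 to 101298430 was at least 13-fold lower, from 58.5 ± 24.8.

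Of 21 IL-10 and STAT3 targets, 6 rose with late IL-10 and none fell (10 adjusted over the list alone, and 10 over all genes with the block), with a list median of 0.65. Bcl3, Il4ra, Nfil3 and Etv3 were among them (camera adjusted p = 1.24e-13, adjusted p = 0.113 with an estimated correlation). Socs3 was 0.80 and Il1rn 1.71 higher, and they passed with the block (adjusted p = 0.0126 and 3.41e-04) but not without it (adjusted p = 0.0596 and 0.152). In the test over regions without the block, the region of Socs3 was called (adjusted p = 0.0440). Nfkbia was 0.85 higher (adjusted p = 0.0972) and passed with the block (0.0250) and without late IL-10 replicate 3 (0.0495). Of 28 cytokine genes only Ccl17 was lower over all genes, at least 5.57-fold (2 adjusted over the list alone, 3 with the block), and its call ended without each library but LPS replicate 3, up to adjusted p = 0.108. For that list camera gave adjusted p = 0.262, and 1.84e-06 without LPS replicate 3 and 0.0115 without late IL-10 replicate 2, and adjusted p = 0.9754 with an estimated correlation. Tnf was 0.72 lower (SE 0.19, adjusted p = 0.0512) and passed with the block (0.0137) and with total-read scaling (0.0123). In the test over regions, its region was called lower (adjusted p = 0.0379).

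No interferon response gene or inflammatory effector was called with late IL-10 with limma, against 1 and 1 higher and 1 and 2 lower at an unadjusted p under 0.05. None was called adjusted over either list alone, and with the block 1 interferon gene was higher and 1 effector went each way. The camera adjusted p was 0.904 for the interferon list and 0.742 for the effectors. Without LPS replicate 3 both lists were lower (adjusted p = 0.0421 for each), and without late IL-10 replicate 3 both were higher (adjusted p = 0.0429 and 0.0334), and in the fit of all libraries both had adjusted p = 0.9754 with an estimated correlation. The fits without a library numbered 3 ignored the pairing and kept its partner in the other group. The response to LPS was weaker in that pool with and without late IL-10. These opposite turns therefore cannot be read as an effect of IL-10. Among 29 macrophage identity genes, Fcgr3 and Pparg (1.34) rose (4 higher and 3 lower adjusted over the list alone, 8 and 5 with the block; camera adjusted p = 0.228, 0.0213 without LPS replicate 2, and adjusted p = 0.970 with an estimated correlation). The call for Pparg ended without late IL-10 replicate 1 (adjusted p = 0.0522). Of 21 NF-kB pathway genes Map3k8 rose (2 higher and 1 lower adjusted over the list alone, 4 and 1 with the block; camera adjusted p = 0.904). Of 20 immediate early genes Ier3 and Dusp1 (1.44) rose (2 adjusted over the list alone; camera adjusted p = 0.228), and the call for Dusp1 ended without late IL-10 replicate 1 or 2 (adjusted p = 0.0566 and 0.0586).

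Elane (5.02), Mmp8 (1.67) and Cpa3 (at least 12.8-fold) were also higher with late IL-10 than with LPS alone. Of the 7 neutrophil markers 2 rose (2 higher and 1 lower adjusted over the list alone and with the block; camera adjusted p = 0.742), and the list median was -0.64 while its mean was 0.39 and camera ranked it upward. Of the 4 erythroid and mast cell markers Cpa3 rose (1 adjusted over the list alone; camera adjusted p = 0.262). The call for Elane ended without LPS replicate 1 or 2 or late IL-10 replicate 1 or 3, and those for Mmp8 and Cpa3 without late IL-10 replicate 1 or 2, up to adjusted p = 0.0956, 0.0915 and 0.0548. No housekeeping, lipid, T cell, B cell, dendritic cell or fibroblast gene was called over all genes or adjusted over its list alone (camera adjusted p = 0.866, 0.188, 0.742, 0.904, 0.963 and 0.970). At an unadjusted p under 0.05, 1 lipid gene was lower, 1 B cell marker higher and 1 dendritic cell marker went each way, and with the block 1 lipid gene was lower and 1 dendritic cell marker higher. Without late IL-10 replicate 3 the lipid list had camera adjusted p = 0.0429, and in the fit of all libraries adjusted p = 0.754 with an estimated correlation.

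**Figure D3:**
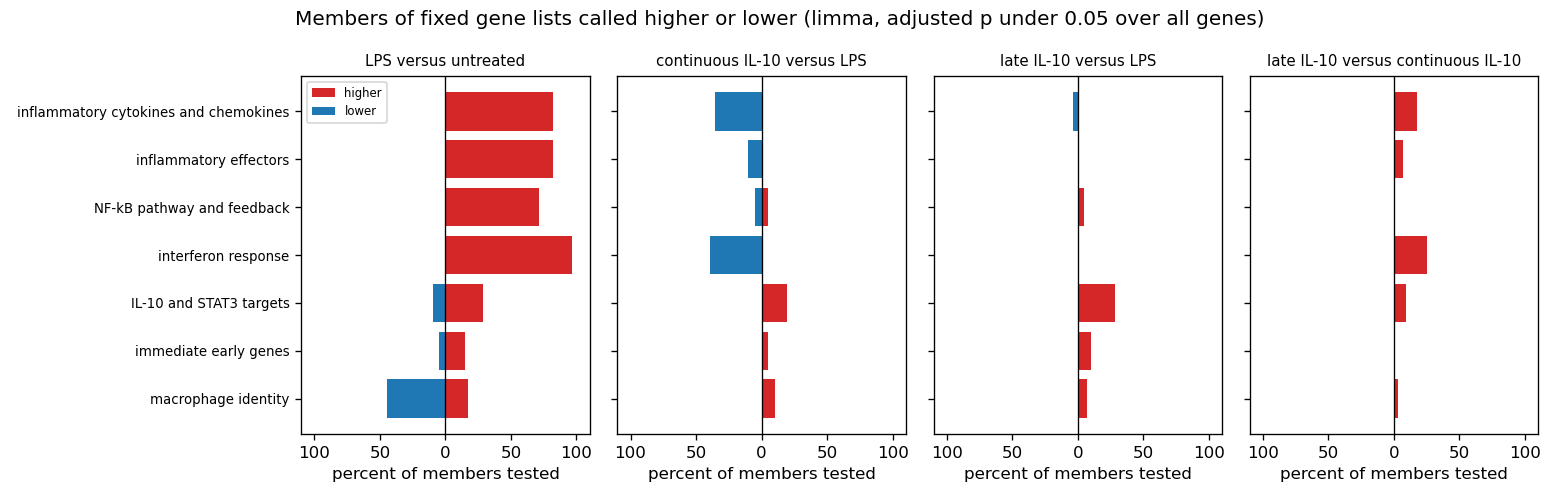
Percent of the tested members of 7 gene lists called higher (right) or lower (left) in each comparison (limma, adjusted p under 0.05 over all genes). Of 28 interferon response genes, 27 were higher with LPS, 11 lower with continuous IL-10, none called with late IL-10, and 7 higher with late than with continuous IL-10.

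The IL-10 schedules were also tested directly against each other. With late IL-10, Il6 was at least 173-fold higher than with continuous IL-10 (5738 ± 4602 against 6.57 ± 1.76, n = 3; adjusted p = 0.0105 from limma). Ccl2, a monocyte chemoattractant gene, was higher by 3.89 (SE 0.63, adjusted p = 0.0150), Rsad2 by 3.31 (SE 0.62, adjusted p = 0.0207) and Irf7 by 2.21 (SE 0.37, adjusted p = 0.0153). These 4 calls ended without continuous IL-10 replicate 2 or late IL-10 replicate 1 or 2, up to adjusted p = 0.0957 for Il6, 0.110 for Ccl2, 0.129 for Rsad2 and 0.125 for Irf7, and those for Rsad2 and Irf7 also without continuous IL-10 replicate 3 (0.0633 and 0.0517). At Tnf the schedules differed by 0.10 (95% interval -0.30 to 0.50, adjusted p = 0.851).

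In all, 680 regions were higher and 312 lower with late than with continuous IL-10, or 2936 and 1818 with the block and 579 and 443 when scaled to total reads. Their median log2 changes were 4.03 and -3.59, or 3.54 and -2.96 with floors at their bound. Leaving out continuous IL-10 replicate 1, 2 or 3 or late IL-10 replicate 1, 2 or 3 gave 379, 129, 226, 50, 96 and 1452 higher and 105, 28, 65, 15, 54 and 883 lower regions. The region 21305 bp from Exoc6 was at least 120-fold higher with late IL-10, and the region overlapping Cd2 at least 27.3-fold lower.

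Of 28 interferon response genes, 7 were higher with late than with continuous IL-10 (25 adjusted over the list alone, and 23 over all genes with the block; camera adjusted p = 3.87e-19, adjusted p = 0.240 with an estimated correlation). Of 28 cytokine genes 5 were higher (13 higher and 1 lower adjusted over the list alone, 16 with the block; camera adjusted p = 2.73e-09, adjusted p = 0.259 with an estimated correlation). Both counts were 0 without continuous IL-10 replicate 2 or late IL-10 replicate 1 or 2, 0 and 2 without continuous IL-10 replicate 3, and 18 and 11 without late IL-10 replicate 3. Of 28 effectors, 2 were higher, among them Cd40 (1.68; 2 adjusted over the list alone, 4 with the block; camera adjusted p = 9.84e-04, adjusted p = 0.403 with an estimated correlation). Of 21 IL-10 and STAT3 targets, Etv3 (1.34) and Bcl6 (1.20) were higher (5 adjusted over the list alone, 7 with the block; camera adjusted p = 4.27e-05, adjusted p = 0.259 with an estimated correlation). Pparg (1.16; macrophage identity, 1 higher and 3 lower adjusted over the list alone, 3 and 8 with the block, camera adjusted p = 0.209) and Batf3 (2.87; dendritic cell markers, 1 each way adjusted over the list alone, 3 higher with the block, camera adjusted p = 0.0519, or 0.0343 with the block, and adjusted p = 0.259 with an estimated correlation, or 0.351 with the block too) were also higher. Ltf was lower (-1.52; neutrophil markers, 1 adjusted over the list alone, 2 with the block, camera adjusted p = 0.0767). The calls for Cd40, Etv3, Bcl6, Pparg, Batf3 and Ltf ended without continuous IL-10 replicate 2 or late IL-10 replicate 1 or 2, at adjusted p = 0.153, 0.114, 0.240, 0.194, 0.127 and 0.240 without late IL-10 replicate 1.

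No NF-kB, immediate early, housekeeping, lipid, T cell, B cell, fibroblast, or erythroid and mast cell gene was called between the schedules with limma. At an unadjusted p under 0.05, 4 NF-kB genes, 4 immediate early genes, 1 lipid gene and 4 T cell markers were higher, and 1 NF-kB gene, 1 immediate early gene, 1 housekeeping gene, 5 lipid genes and 1 fibroblast marker were lower. With the block, 3 NF-kB genes, 3 immediate early genes, 2 lipid genes and 4 T cell markers were higher, and 1, 1, 1, 6 and 1 genes of the NF-kB, immediate early, housekeeping, lipid and fibroblast lists were lower. Adjusted over the list alone, 4 T cell markers and 1 lipid gene were higher and 2 lipid genes and 1 fibroblast marker lower. The camera adjusted p was 0.0707 for the NF-kB list (0.0343 with the block, and adjusted p = 0.634 with an estimated correlation), 0.199 for immediate early genes, 0.0682 for lipid genes, 0.926 for B cell, 0.292 for fibroblast, and 0.668 for erythroid and mast cell markers. T cell markers were higher (camera adjusted p = 0.00599, adjusted p = 0.199 with an estimated correlation). Housekeeping genes were lower (camera adjusted p = 0.0490, adjusted p = 0.634 with an estimated correlation), a call that ended without continuous IL-10 replicate 1 or 2 or late IL-10 replicate 1 or 3, up to adjusted p = 0.0944. Without late IL-10 replicate 3 the NF-kB and dendritic cell lists had adjusted p = 0.00470 and 0.0440, and without continuous IL-10 replicate 1 they had 0.0164 and 0.0338. Without continuous IL-10 replicate 3 the macrophage identity, lipid and neutrophil lists had 0.0494, 0.0474 and 0.0494, and without late IL-10 replicate 2 the macrophage identity list had 0.0235. In the fit of all libraries the dendritic cell, macrophage identity, lipid and neutrophil lists had adjusted p = 0.259, 0.634, 0.377 and 0.259 with an estimated correlation.

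Of the 6053 regions raised by LPS, 851 (14.1%) were lower with continuous IL-10, against 1.10% of the other regions tested (Fisher's exact test, odds ratio 14.8; regions are not independent). With late IL-10, 61 (1.01%) were lower, against 0.275% of the others (odds ratio 3.69). Their median log2 change was -1.14 with continuous and -0.38 with late IL-10, or -1.11 and -0.37 with floors at their bound. The LPS libraries enter both the selection and the comparison. Unchanged groups, simulated without a pool effect, gave medians of -0.15 for both. There all libraries, those with LPS included, were redrawn around the observed group means, with both IL-10 groups at the LPS mean. These means already hold the chance part of the real LPS libraries, so the simulated shift may be too small. In these simulated groups 0.000665% of LPS-raised regions were lower with continuous and 0.00133% with late IL-10. With regions selected on 2 LPS libraries and compared with the one left out, 1.81% and 0.139% were lower, against 0.162% and 0.0887% of the other regions, as means over the 3 LPS libraries left out. That test has a single LPS library, assumed to vary like the other groups, and so less power, so how much of the full shares comes from the selection was not decided. With the block 27.3% and 2.87% were lower. In the cross-fitted selection all libraries of an IL-10 group were compared with 1 LPS library, which ignores the pairing. The medians against LPS replicates 1, 2 and 3 were -1.64, -1.81 and 0.10 with continuous and -0.78, -0.88 and 0.95 with late IL-10. The direction against LPS replicate 3 thus differed from that against the others. Within pools 1, 2 and 3, over regions selected without that pool, the medians were -1.18, -1.32 and -0.35 with continuous IL-10. They were -0.33, -0.47 and 0.09 with late IL-10, so within pools continuous IL-10 kept its direction. The share lower with continuous IL-10 was 6.10%, 6.04%, 26.1%, 6.62% and 6.14% without LPS replicate 1, 2 or 3 or continuous IL-10 replicate 2 or 3, and its median was -1.80 without LPS replicate 3. The share lower with late IL-10 was 0.537%, 0.409% and 0.308% without LPS replicate 1 or 2 or late IL-10 replicate 1, and its median was -0.90 without LPS replicate 3 and 0.02 without late IL-10 replicate 3. Of the 6573 regions lowered by LPS, 694 (10.6%) were higher with continuous and 494 (7.52%) with late IL-10, against 1.69% and 2.18% of the others. With the block it was 1659 (18.2%) and 964 (10.6%) of 9128. The medians of the 6573 regions were 0.74 and 0.11, or 0.68 and 0.29 with floors at their bound, against 0.15 for both in the simulated groups, which were not computed at the bound.

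Across regions, the log2 changes of the IL-10 schedules against LPS correlated with r = 0.507, and their covariance was 1.08. Simulated unchanged groups that share redrawn LPS libraries gave 0.502 and 0.441. The simulated groups carry no pool effect, so these values ignore the pairing of the libraries. With each schedule compared with LPS within a pool and the schedules taken from different pools, so that no library was shared, r was 0.160 to 0.355 over 6 pairs of pools (mean 0.259), a comparison chosen after seeing the data. The r was 0.653 without LPS replicate 3 and 0.320 without late IL-10 replicate 3. There were 632 regions higher and 50 lower in both, where independent lists of these sizes would share 37.7 and 4.70 and simulated unchanged groups 0 and 0.05. Part of the excess may come from the shared LPS libraries, as the overlap was not computed with different ones. Of the 1186 regions lower with continuous IL-10, 426 also differed directly between the schedules.

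Regions away from gene ends were called more often than those within 1 kb of one. With LPS, 18.8% of 24990 such regions rose and 21.1% fell, against 11.6% and 11.1% of 11631 at gene ends (odds ratios 1.76 and 2.14). With continuous IL-10 the odds ratios were 2.08 for rises and 1.48 for falls, with late IL-10 1.76 and 2.04, and between the schedules 1.36 and 2.51. Within strata of equal abundance they were 2.42 and 1.87 for LPS, 3.23 and 1.54 for continuous IL-10, 2.87 and 2.21 for late IL-10, and 1.56 and 3.45 between the schedules.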

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

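The tests of mixing and of lower enrichment in the pool numbered 3, the last of which was also changed after its result was seen, and of scaling for the rises with late IL-10, were chosen only after the results were seen. The results named first are those where late and continuous IL-10 differed in a direct test with limma. Late IL-10 had 680 regions higher and 312 lower than continuous IL-10. The camera adjusted p was 3.87e-19 for the interferon response, 2.73e-09 for cytokines and chemokines, 9.84e-04 for inflammatory effectors, 4.27e-05 for IL-10 and STAT3 targets and 0.00599 for T cell markers, all higher with late IL-10, and 0.0490 for housekeeping genes, which were lower. The housekeeping call ended without continuous IL-10 replicate 1 or 2 or late IL-10 replicate 1 or 3, up to 0.0944. None of these lists passed with the correlation estimated, and in the same order they had adjusted p = 0.240, 0.259, 0.403, 0.259, 0.199 and 0.634 with an estimated correlation. Among genes, the fitted log2 differences were 2.11 for Cxcl10, 2.77 for Cxcl9, 3.89 for Ccl2, 1.68 for Cd40, 2.21 for Irf7, 3.31 for Rsad2, 3.55 for Cmpk2, 1.65 for Stat2, 1.34 for Etv3, 1.20 for Bcl6, 1.16 for Pparg, 2.87 for Batf3 and -1.52 for Ltf. The fitted value for Il6 was 8.80, which is no bound, and the deposited values give at least 173-fold. Each of these 14 gene calls ended without continuous IL-10 replicate 2 or late IL-10 replicate 1 or 2. Those for Bcl6, Cd40, Ltf and Pparg also ended without continuous IL-10 replicate 1, and those for Cxcl10, Cxcl9, Cd40, Irf7, Rsad2, Cmpk2, Stat2, Etv3, Bcl6 and Ltf without continuous IL-10 replicate 3. Without late IL-10 replicate 1 the adjusted p was 0.0957 for Il6, 0.128 for Cxcl10, 0.156 for Cxcl9, 0.108 for Ccl2, 0.153 for Cd40, 0.125 for Irf7, 0.129 for Rsad2, Cmpk2 and Stat2, 0.114 for Etv3, 0.240 for Bcl6, 0.194 for Pparg, 0.127 for Batf3 and 0.240 for Ltf.

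Among regions, the fitted log2 differences between late and continuous IL-10 were 9.90 near Il6 (at least 568-fold), 7.65 near Exoc6 (at least 120-fold), 7.07 at Pappa2, 6.75 near Lipg, -6.15 at Zdhhc14 (at least 40.9-fold lower), -5.58 at Cd2 (at least 27.3-fold lower), -5.50 near Pde3b (at least 25.9-fold lower) and -5.45 near Bin1. The calls near Lipg, at Zdhhc14, near Pde3b and near Bin1 ended without continuous IL-10 replicate 2 or late IL-10 replicate 1 or 2. Those near Lipg, at Zdhhc14 and near Pde3b also ended without continuous IL-10 replicate 3, and that near Pde3b without continuous IL-10 replicate 1. Where a call ended, the log2 difference was between 4.83 and 7.03 for the region at Lipg, -6.25 and -6.01 for the region at Zdhhc14, -5.89 and -4.77 for the region at Pde3b and -5.63 and -4.79 for the region at Bin1. Leaving out late IL-10 replicate 1 gave 50 regions higher and 15 lower in all, and leaving out late IL-10 replicate 3 gave 1452 and 883.

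With 3 libraries against 3 there are 10 splits of the 6, which cannot give a share under 0.05. The real split, 1 of the 10 splits, called 12626 regions for LPS against untreated, where the highest of the others called 0. It called 2387 for continuous IL-10 against 6, 1294 for late IL-10 against 28, and 992 between the schedules against 25. Among the 4 splits that part all 3 same-numbered pairs, the highest other called 0 in each comparison. Every other split mixes both groups in each part, so a real difference widens the spread and keeps its calls low. The low counts therefore do not measure how many calls would arise without a difference.

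In the pool numbered 3 the response to LPS was weaker, with a median log2 difference of 2.27 over 84 genes of the response lists, against 3.10 and 3.50 in the pools numbered 1 and 2, and its medians against untreated were also lower with late IL-10 (2.52 against 3.27 and 3.61) and continuous IL-10 (0.99 against 1.73 and 1.35). A larger total of reads in regions was argued against, as the LPS median was 2.16 after thinning every library to the same total, against 3.10 and 3.48. Untreated chromatin mixed into the LPS library would keep 1 share of every gene's rise. But the quartiles of the share kept were 20.0% and 57.4% over 73 genes, 9 of which kept at least 90% where 0 were expected. Its spread on the log2 scale was 4.204 times that between LPS replicates 1 and 2, which argues against mixing as the only cause. The share divides the rise in pool 3 by that in the other pools, so gene differences between pools widen it too. Mixing beside such differences was not excluded. Lower enrichment in the LPS library stays open, since 2 comparisons differ. The regions LPS lowered in pools 1 and 2 had a median of -2.52 in pool 3, against -3.59 and -3.29 in the pools that selected them. Over other, fewer regions that each of those pools did not select, their medians were -4.26 and -4.23. There the smaller fall of pool 3 meets what lower enrichment predicts. A fault in that LPS library alone would not account for the weaker IL-10 libraries. However, the medians of pool 3 with LPS and with both IL-10 schedules are all taken against untreated replicate 3, so they are not independent. A difference between the pools of cells was not tested.

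Interferon response genes were higher with late than with continuous IL-10, with a list median of 1.64, but only 7 of 28 genes were called and the list call was lost with an estimated correlation (adjusted p = 0.240, or 0.106 with the block). Scaling was argued against, since the lowest list median over 4 other scalings was 1.43. A difference in total reads was argued against, since the lowest of the 3 pools gave 1.32 after thinning. Few list genes share a region, as the 28 genes form 26 groups that share none, with a median of 1.62. So few genes were merged that the median could hardly move, and this value adds no separate support. A difference due to the IL-10 schedule may underlie it, as a hypothesis found and tested on the same data. None of the list's single genes is called without continuous IL-10 replicate 2 or late IL-10 replicate 1 or 2.

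Of the regions called with late IL-10, 88.8% were rises. Scaling was argued against as the whole cause, since the lowest share over 4 other scalings was 85.4%, and total reads likewise, with 88.4% after thinning. The share was 76.2% with the replicate block and 77.7% without the 4 libraries numbered 3. A difference due to late IL-10 itself stays open and was not tested.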

How the results depend on the processing

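Chosen after seeing the data were edgeR on the recovered reads, edgeR with the block, the block with a pseudocount of 10, leaving out the 4 libraries numbered 3, and correlating the schedules from different pools. The planned search for sequence motifs was not run. The LPS counts, 6053 higher and 6573 lower, stayed within 1.5 times under each alternative run except for 9902 lower with the block and a pseudocount of 10. Higher and lower counts with continuous IL-10 (1201 and 1186) were 2719 and 3287 with the replicate block, 346 and 293 with only the groups compared in the fit, 1899 and 2771 with DESeq2, 2502 and 3332 with edgeR and the block, 3034 and 4081 with the block and a pseudocount of 10, and 1926 and 3402 without the libraries numbered 3. With late IL-10 (1149 and 145) they were 2258 and 704, 281 and 2, 1760 and 409, 2120 and 635, and 2675 and 1025 in the same order, and 396 lower without the libraries numbered 3. Between the schedules (680 and 312) they were 2936 and 1818, 141 and 25, 2216 and 936, 2831 and 1445, and 3736 and 2285 in the same order, 3052 and 1340 without the libraries numbered 3, 196 lower with edgeR and 510 lower with quantile normalization. The share of LPS-raised regions lower with continuous IL-10 (14.1%) was 1.81% with cross-fitted selection, which also leaves 1 LPS library to compare with, 27.3% with the block and 30.7% without the libraries numbered 3, and with late IL-10 (1.01%) 0.139%, 2.87% and 1.75%. The fit of only the groups compared has fewer libraries to estimate the spread, and the cross-fitted comparison has fewer LPS libraries. Its medians averaged -1.12 over the LPS libraries left out with continuous IL-10, against a median of -1.14 in the full fit. With late IL-10 the average was -0.23 against -0.38. These averages hide medians of 0.10 and 0.95 against LPS replicate 3, opposite in sign to those against the other LPS libraries. The correlation of the schedules (0.507) was 0.259 with the schedules from different pools, which removes the shared LPS libraries but compares single libraries. For the other changes the cause was not tested.

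With 1 library left out, continuous IL-10 gave between 584 and 1751 higher and 373 and 2777 lower regions, late IL-10 between 596 and 1149 higher and 38 and 278 lower, and late against continuous IL-10 between 50 and 1452 higher and 15 and 883 lower. The share of LPS-raised regions lower with continuous IL-10 lay between 6.04% and 26.1% and their median between -1.80 and -0.91. With late IL-10 the share lay between 0.308% and 1.34% and the median between -0.90 and 0.0193, a reversal without late IL-10 replicate 3. The correlation of the schedules lay between 0.320 and 0.653. Without LPS replicate 3 the interferon and effector lists turned lower with late IL-10, at camera adjusted p = 0.0421 each, and the range over the 6 libraries was 0.0421 to 0.646 and 0.0334 to 0.879. A group left with 2 libraries was assumed to vary like the others. These fits were unpaired, so leaving out 1 library kept its partner of the same pool in the other group. The shifts thus include any difference between pools, and the cause was not tested further.

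Of 1322 values of named genes under other settings, 1228 kept their direction and side of the threshold, 61 lost the call and 33 gained one, and with 1 library left out 686 of 882 did, 193 lost it and 3 gained one. For named regions it was 708 of 728 and 294 of 336, and the rest lost the call. For camera tests it was 561 of 600 (16 gained, 23 lost) and 323 of 360 (19 gained, 16 lost, 2 turned). Counts of list members stayed within 1.5 times in 519 of 711 and 322 of 474. Besides the calls given with the results, the replicate block changed those for Il12b (4.69), Ifnb1 (1.07), Bcl3 (0.81) and Il1rn (1.38) between the schedules, which were higher with late IL-10 and passed with the block (adjusted p = 0.00165, 0.0227, 0.0109 and 0.00212) but not without it (0.0628, 0.139, 0.105 and 0.219). Median centring shifted all log2 changes by 0.24 with LPS, by 0.11 with continuous IL-10 and by -0.12 between the schedules, and total reads by -0.12 with LPS and -0.19 between the schedules. Depth limits weak regions, and thinning every library to the same total of reads in regions gave 5660 and 6630, 1205 and 1214, 1194 and 157, and 769 and 357 calls in the order above.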

Other observations

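The tests here were written before their results were seen. Regions that LPS raised and continuous IL-10 lowered may have carried less H3K27ac before LPS. Within strata of equal LPS level, their mean log2 untreated value was lower than that of other LPS-raised regions by a difference of -0.32 (1000 permutations, p = 0.000999, the smallest they can give; regions are not independent). The untreated libraries were all at the floor in 46.7% of the 851 lowered and 36.9% of the 5202 other regions. The difference lay between the bounds of -0.5 and -0.2 set in advance, so the hypothesis stays undecided.

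A rise that is larger 30 min after IL-10 than 195 min after it was tested over 1718 regions raised by either schedule. The median of late minus continuous IL-10 was 0.15, 0.47 and 0.10 in pools 1, 2 and 3, and the lowest, 0.10, was too small to decide. Over the 21 IL-10 and STAT3 targets it was 0.42, 0.69 and 0.27.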
